A study of Homo sapiens with 6 samples.

How the data were processed

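RNA from the human melanoma lines WM115, derived from a primary skin tumour, and WM266-4, derived from a skin metastasis, was measured on Affymetrix gene-level arrays. Both lines were grown in DMEM with 10% foetal bovine serum. The design had 3 biological repeats of each line, so 6 arrays. Per the labels' protocols, RNA of the first repeat was prepared with the miRNeasy micro kit and hybridised to Human Gene 1.0 ST arrays, and RNA of repeats 2 and 3 was prepared with the GeneAll Hybrid-R miRNA kit and hybridised to Human Gene 2.1 ST arrays. Array version, RNA kit and repeat therefore changed together, and each array version held both lines.

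Per the submitters' processing notes, Affymetrix Expression Console and RMA (robust multi-array averaging) were used, with no version or order of steps. RMA summarises background-corrected, quantile-normalized probe signals. The gene-named table deposited by the authors gave log2 signals of all 6 arrays on one scale. In it the mean of each gene over the 1.0 pair nearly equalled its mean over the 2.1 arrays, with a median absolute difference of 0.0031 log2 and a largest of 0.11, so an array-version effect had been removed gene by gene before deposit. How this was done is not given in the sources used here. Whether it changed the size of the difference between the lines within a version could not be tested without gene names for the value tables. Such a step spreads a change in one line of a pair over both lines' levels, so the level of one line in the first repeat cannot be set against its level in the later repeats. The series value tables deposited per array version held log2 values for 33297 probe sets on the 1.0 arrays, with a median of 5.41, and 53617 on the 2.1 arrays, with a median of 3.06. Their probe sets were not paired with gene names here, and how they were scaled is known only from the processing notes. The array medians in the gene-named table, over the genes tested, lay between 6.12 and 6.18. No detection calls or scanner signals were used here, so signal over background was not assessed and a level near the bottom of the scale is not read as absence. The number of arrays limits the precision.

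The gene-named table had 18887 rows. Rows naming several genes (24) were left out, and of 1110 rows that repeated a symbol the brightest row per gene was kept, leaving 17753 genes, 17703 of which matched a current symbol or synonym in RefSeq for GRCh38.p14. Genes below the 30th percentile of the mean over all arrays (3.97 log2) were not tested, which left 12427. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior) with line and array version as terms, giving 3 residual degrees of freedom and 3.38 prior degrees of freedom. P values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Adjusted p values for genes come from this limma fit. Differences are WM266-4 minus WM115, and "rose" and "fell" mean called higher and called lower in WM266-4. Errors of levels are SDs over 3 arrays, and errors of differences are standard errors of the fit. The removal of the array-version effect before deposit enters these SDs.

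The groups, the fit, the filter, 28 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took SNX18, CDC42 and RHOA; the 10 largest increases and 10 largest decreases among called genes with one sign in every pair of repeats; and up to 2 called members per list and direction. XIST, Y-linked genes and unnamed or clone-named transcripts were not eligible among the largest changes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, with an estimated correlation beside it. On simulated data without changes, 0% of 200 random lists of 30 genes had a camera p under 0.05 with an estimated correlation. The preset correlation gave 2.5%, so the estimated form was strict for these simulated lists. The simulated genes were drawn independently, so these shares do not show how either form behaves for lists of correlated genes. The fry test asked whether a list's genes moved, on balance, one way, and its mixed form whether they changed in either direction; neither compares a list with other genes. Older symbols were matched through synonyms only where the listed symbol was missing from the table; this rule was set after the first run had matched 2 unrelated genes. Lists covered, among others, sorting nexins, melanoma states, adhesion, matrix, cell cycle, antigen presentation, interferon, cytokines, signalling, metabolism, autophagy, endocytosis and markers of other cell types, and 44 genes stood in more than 1 list. Some lists and genes that the rule took are not reported here.

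Replicates of a line were compared before averaging. None shared identical values, and the SD of their differences over genes ran from 0.22 to 0.34 log2. The removal of the array-version effect enters the SDs that involve replicate 1. The fit was tested on simulated data for the 12427 genes with the real spreads. It recovered 7.46% of 67 genes changed by 0.5 log2, 92.5% of 67 changed by 1 and 97.0% of 66 changed by 2. Of its 140 calls, 9 were unchanged genes. Far fewer genes changed there than the 3341 called in the real data, which makes the Benjamini-Hochberg cut stricter. These shares therefore may not carry over to the real fit. Alternatives covered the filter, the variance prior, the rows per gene, the scaling, the replicate number as a block, the 2.1 arrays alone, the 2.1 value table, stricter thresholds and leaving out each array in turn. With 1 first-repeat array left out, the array-version term absorbs the other, so the difference comes from the 2.1 arrays alone. Leaving out either first-repeat array and using the 2.1 arrays alone are therefore 1 check. A fit without the array-version term was added after the data were examined.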

Results

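Gene expression was compared between WM115, a melanoma line from a primary skin tumour, and WM266-4, a line from a skin metastasis. The series title concerns the sorting nexin SNX18 and the GTPases CDC42 and RHOA in melanoma migration. Each line was measured on 3 arrays of separate biological repeats, the first on Human Gene 1.0 ST arrays and repeats 2 and 3 on Human Gene 2.1 ST arrays. Levels are log2 signals as deposited, and differences are WM266-4 minus WM115.

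Among the largest increases in WM266-4 were pigment-cell genes. Of 37 tested pigmentation genes, 25 rose, 1 fell and 11 were not called. TYR, the rate-limiting enzyme of melanin synthesis, stood at 3.17 ± 0.26 in WM115 and 10.08 ± 0.31 in WM266-4 (SD, n = 3), a difference of 6.91 log2 (SE 0.20, adjusted p = 3.2e-05). DCT, which acts downstream of tyrosinase, rose by 6.43 (SE 0.74), the melanosomal exchanger SLC24A5 by 6.02 (SE 0.54) and the melanosome matrix protein PMEL by 5.34 (SE 0.64). In the other direction, the inflammatory cytokine IL1B stood at 9.15 ± 0.45 in WM115 and 2.63 ± 0.37 in WM266-4, a difference of -6.53 (SE 0.28, adjusted p = 0.00011). The Wnt antagonist SFRP1 fell by 5.79 (SE 0.13), the vascular ligand ANGPT2 by 5.61 (SE 0.19) and the cadherin CDH13 by 5.39 (SE 0.15).

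The remaining largest increases were the secreted proteins PI15 (5.06) and NELL1 (4.88), the fatty acid elongase ELOVL2 (4.81), the glycosyltransferase GALNT5 (4.61), the collagen chain COL1A2 (4.48) and RAB38 (4.43), a small GTPase of melanosome transport. The remaining largest decreases were the phosphoinositide 3-kinase subunit PIK3CG (-5.43), the neurofilament NEFL (-5.38), the adhesion protein CLMP (-5.07), the heparan sulfatase SULF1 (-5.06), the metalloproteinase PAPPA (-4.99) and the plasminogen activator inhibitor SERPINB2 (-4.97).

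Of 12427 genes tested, 3341 were called by limma, 1689 higher and 1652 lower in WM266-4. The calls made up 26.9% of the genes tested, and the counts given for a list are to be read beside that share. An absolute difference of at least 1 log2 was reached by 443 of the higher and 529 of the lower genes. Of called genes, 99.97% had one sign in all 3 pairs, a share nearly fixed in advance because the calls use the same pairs. Among genes called on the 2.1 arrays alone, 86.8% had the same sign in the first-repeat pair. The count of 3341 depended on which arrays were fitted. It was 1776 without WM115 replicate 2, 1805 without WM115 replicate 3, 1381 without WM266-4 replicate 2 and 1687 without WM266-4 replicate 3. Of those 1381 genes, 1363 were among the 3341. The count was 3895 without WM115 replicate 1 and 3924 without WM266-4 replicate 1, where the 2.1 arrays alone give the difference.

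SNX18, a membrane-remodelling sorting nexin, was lower in WM266-4. Its level was 6.15 ± 0.23 in WM115 and 5.57 ± 0.18 in WM266-4 (SD, n = 3), so the mean signal of WM115 was 1.49 times that of WM266-4. The difference was -0.58 log2 (SE 0.16, 95% interval -0.96 to -0.19, adjusted p = 0.043 by limma), and the pairs gave -0.17, -0.92 and -0.64. CDC42, a GTPase that drives filopodia, had 8.04 ± 0.11 and 8.10 ± 0.10, a difference of 0.07 (SE 0.11, interval -0.21 to 0.34, adjusted p = 0.71). RHOA, a GTPase that drives contractility, had 10.51 ± 0.01 and 10.60 ± 0.07, a difference of 0.08 (SE 0.10, interval -0.15 to 0.32, adjusted p = 0.58). The 39 genes that share a window of neighbouring genes with SNX18 had a median difference of -0.31. These are transcript levels and do not measure GTPase activity. The SNX18 call was lost without a filter on dim genes (adjusted p = 0.0501) and after quantile normalization (0.0521). It was also lost without WM115 replicate 2 (0.115), WM115 replicate 3 (0.104), WM266-4 replicate 2 (0.154) or WM266-4 replicate 3 (0.144). The CDC42 difference turned to -0.03 on the 2.1 arrays alone. Leaving out WM115 replicate 1 or WM266-4 replicate 1 gave the same value, since the 2.1 arrays then give the difference. The CDC42 difference was 0.13 without WM115 replicate 3 or WM266-4 replicate 2. The RHOA difference was 0.04 without WM266-4 replicate 3 and 0.16 after quantile normalization.

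**Figure D1:**
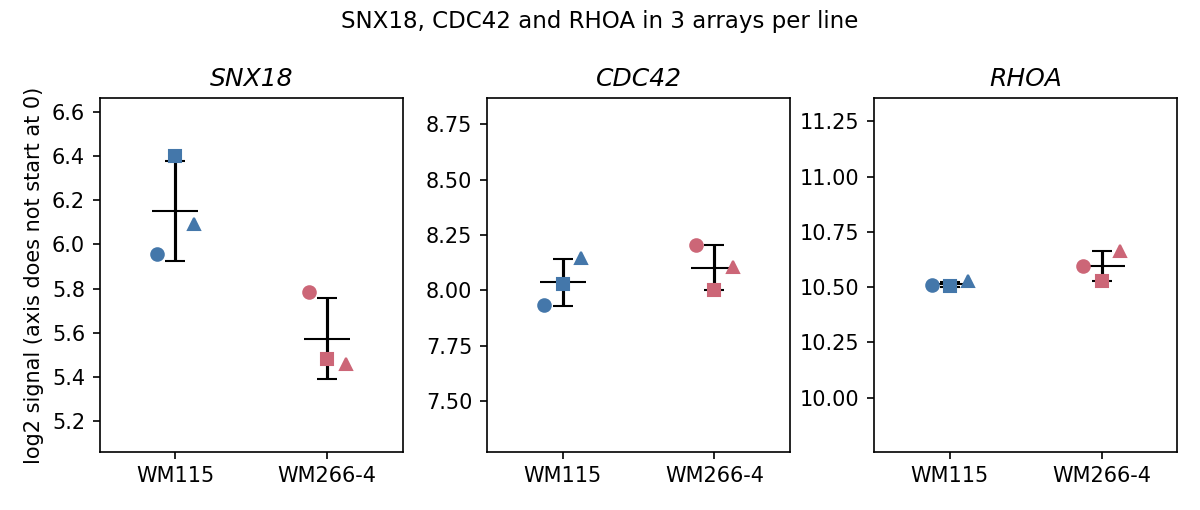
Log2 signal of SNX18, CDC42 and RHOA in WM115 and WM266-4, with circles for repeat 1, squares for repeat 2, triangles for repeat 3, and bars for the mean and SD of 3 arrays. SNX18 was lower in WM266-4 in each pair, by 0.17 at the least, while the CDC42 and RHOA means differed by 0.07 and 0.08 log2.

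Among 37 tested genes of pigmentation and melanocyte differentiation, 25 rose, 1 fell and 11 were not called (27 rose and 1 fell adjusted over the list alone). TYR and DCT led the increases, and IRF4, a transcription factor active in melanocytes, fell by 0.94 (SE 0.15, adjusted p = 0.0073). MITF, the transcription factor of the melanocyte lineage, was singled out after its values were seen; it rose by 2.83 (SE 0.13, adjusted p = 0.00014). The list median was 1.31 (camera adjusted p = 1.8e-10; adjusted p = 0.37 with an estimated correlation). It was 1.37 in the first repeat and 1.03 in the later ones, and in a test between array versions, added after the data were examined, 9 members were lower and 3 higher later (camera adjusted p = 0.0026; adjusted p = 0.91 with an estimated correlation). Of 48 genes of an invasive or dedifferentiated melanoma state, 30 fell, 1 rose and 17 were not called (34 fell and 1 rose adjusted over the list alone). CDH13 and the potassium channel KCNMA1 (-4.26, SE 0.13) fell most, and the growth factor TGFB2 rose by 3.07 (SE 0.23). The median was -1.01 (camera adjusted p = 1.7e-10; adjusted p = 0.22 with an estimated correlation).

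Cell cycle genes were higher in WM266-4: 33 of 50 rose, none fell and 17 were not called (40 rose adjusted over the list alone). The proliferation antigen MKI67 rose by 1.31 (SE 0.15) and the mitotic kinase CDK1 by 1.27 (SE 0.12). The median was 0.50 (camera adjusted p = 3.4e-11; adjusted p = 0.22 with an estimated correlation). Of 20 genes of MHC class I antigen presentation, 9 fell, 0 rose and 11 were not called (10 fell adjusted over the list alone). HLA-C, a class I heavy chain, fell by 1.07 (SE 0.14), although probes for similar HLA genes may cross-hybridise. The median was -0.50 (camera adjusted p = 0.00065; adjusted p = 0.37 with an estimated correlation). Of 21 chemokines and cytokines, 7 fell, 1 rose and 13 were not called (8 fell and 2 rose adjusted over the list alone). IL1B and IL1A (-4.70, SE 0.21), both interleukin-1 ligands, fell most, and TGFB2 rose. The median was -0.41 (camera adjusted p = 0.035; adjusted p = 0.37 with an estimated correlation, and 0.0516 with the preset one without WM115 replicate 2). These were the 5 of 28 lists called with the preset correlation, and 0 were called with an estimated one. Without the filter on dim genes 11 were called with the preset one, the other 6 being cholesterol biosynthesis, cancer-testis antigens, MHC class II, type I interferon response, autophagy and MAPK output (adjusted p from 0.033 to 0.047; from 0.31 to 0.55 with an estimated correlation). For the cytokines the estimated correlation was -0.030, under the preset 0.01, yet the unadjusted camera p went from 0.0062 to 0.058. For the cytokines, the miss with an estimated correlation thus does not show that correlation between genes explains the result. The estimated correlation of the other called lists was above the preset one. It was 0.18 for pigmentation, 0.067 for MHC class I, 0.038 for the invasive state and 0.023 for the cell cycle. For those lists correlation between genes stays a possible reason for the miss. By fry 12 lists moved one way on balance, and by its mixed form 26 held genes that changed in either direction.

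Sorting nexins and endocytic genes moved both ways, as did the tested genes as a whole, of which 26.9% were called. Of 26 sorting nexins, 3 rose, 5 fell and 18 were not called (the same counts adjusted over the list alone). The endosomal sorting nexins SNX4 (0.64, SE 0.13) and SNX1 (0.62, SE 0.11) rose most, and SNX29 (-0.82, SE 0.12) and SNX16 (-0.81, SE 0.13) fell most. Of 44 BAR domain and dynamin endocytic proteins, 2 rose and 3 fell (2 and 3 adjusted over the list alone), led by the kinase FES (0.93, SE 0.11) and amphiphysin AMPH (-1.93, SE 0.24). The camera adjusted p was 0.73 for each list. The SNX4 call (adjusted p up to 0.078) was lost on leaving out any 1 array of repeats 2 or 3, and the SNX1 call (0.056) without WM266-4 replicate 2.

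**Figure D2:**
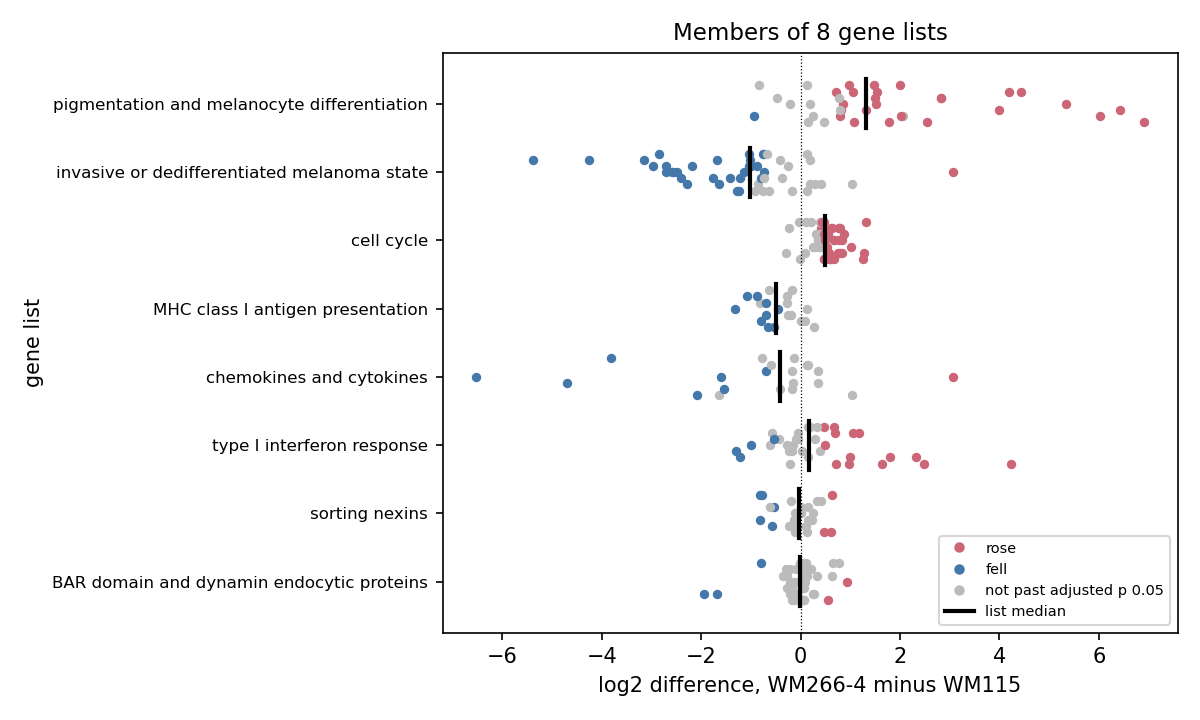
Log2 difference between WM266-4 and WM115 for each tested member of 8 gene lists; red points rose, blue points fell, grey points were not called, and the black bar is the list median. Medians ran from -1.01 for the invasive state to 1.31 for pigmentation, and those of the sorting nexins and the endocytic proteins were -0.02 and -0.01.

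Adhesion and matrix genes changed in both directions. Of 18 cadherins and EMT regulators, 3 rose and 6 fell (3 and 8 adjusted over the list alone); the tight junction protein CLDN1 rose by 3.37 (SE 0.35), and CDH13 and the adhesion molecule NCAM1 (-3.86, SE 0.27) fell. Of 17 integrins, 3 rose and 5 fell (4 and 6 adjusted over the list alone), with ITGA9 at 2.44 (SE 0.28) and the collagen receptor subunit ITGA11 at -3.19 (SE 0.69). Of 38 matrix proteases and inhibitors, 5 rose and 11 fell (5 and 12 adjusted over the list alone), with the metalloproteinase ADAM19 at 3.99 (SE 0.45) and SERPINB2 at -4.97. Of 48 collagens and matrix proteins, 8 rose and 10 fell (10 and 11 adjusted over the list alone), with COL1A2 at 4.48 (SE 0.75) and fibrillin FBN2 at -3.04 (SE 0.17). Their median was -0.06, the sign of the test, and their mean 0.08. Camera adjusted p values were 0.17, 0.24, 0.45 and 0.74, while by fry the cadherins (adjusted p = 0.016) and the integrins (0.0066) moved down on balance and the other 2 lists did not pass (0.11 and 0.38). The ITGA11 pairs gave -5.58, -2.34 and -1.64; its difference was -1.99 without WM115 replicate 1 or WM266-4 replicate 1, and its call was lost on leaving out WM115 replicate 2 or 3 or WM266-4 replicate 2 (adjusted p up to 0.069).

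The signalling and metabolic lists and the cancer-testis antigens did not pass the camera test with the filter on dim genes. Of 24 MAPK output genes, 4 rose and 9 fell (4 and 11 adjusted over the list alone), with the feedback inhibitor SPRY1 at 1.89 (SE 0.23) and the receptor EPHA2 at -3.31 (SE 0.26). Of 36 immediate early and stress genes, 4 rose and 6 fell (4 and 8 adjusted over the list alone), and the AP-1 subunit JUN fell by 2.43 (SE 0.14). Of 36 type I interferon response genes, 14 rose and 4 fell (14 and 6 adjusted over the list alone), with the antiviral proteins BST2 at 4.22 (SE 0.16) and IFITM1 at 2.49 (SE 0.14), and SAMD9L at -1.30 (SE 0.24). Of 35 hypoxia and glycolysis genes, 7 rose and 3 fell (7 and 5 adjusted over the list alone), with carbonic anhydrase CA12 at 2.81 (SE 0.26) and the glucose transporter SLC2A3 at -1.68 (SE 0.22). Of 24 cholesterol biosynthesis genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with the isomerase IDI1 at 0.73 (SE 0.11). Of 35 autophagy genes, 4 rose and 11 fell (5 and 13 adjusted over the list alone), with the lysosomal protein LAMP1 at 0.63 (SE 0.10). The ubiquitin-like protein GABARAPL1 was at -1.19 (SE 0.26) and ATG16L1 at -1.05 (SE 0.16). Of 9 cancer-testis antigens, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with SSX1 at 3.00 (SE 0.26) and MAGEA1 at -1.95 (SE 0.31). Camera adjusted p values were 0.090, 0.10, 0.11, 0.64, 0.089, 0.063 and 0.089. By fry the stress (adjusted p = 0.040) and autophagy (0.043) lists moved down on balance and the cholesterol (0.0054) and cancer-testis (0.012) lists up. On leaving out WM266-4 replicate 2 or 3 the calls of SAMD9L (adjusted p up to 0.060) and GABARAPL1 (0.081) were lost.

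Markers of other cell types showed no shared direction. Of 9 fibroblast markers, 2 rose and 3 fell (2 and 3 adjusted over the list alone), with COL1A2 at 4.48 and COL3A1 at -2.01 (SE 0.29), and their median was -0.10 and their mean 0.15. Of 4 keratinocyte markers only desmoplakin DSP fell (-1.48, SE 0.37), of 7 leukocyte markers only the lysosomal protein CD68 (-1.76, SE 0.40), and of 4 endothelial markers only the receptor KDR (-1.91, SE 0.26); none rose. Adjusted over the list alone, 1, 1 and 2 members fell in these 3 lists. The leukocyte list had a median of 0.13, the sign of its test, and a mean of -0.11. Of 20 Schwann and neural crest markers, 5 rose and 2 fell (6 and 3 adjusted over the list alone), with the nuclear receptor RXRG at 3.64 (SE 0.48) and the stem cell factor SOX2 at -2.58 (SE 0.44). This list had medians of -0.10, 0.44 and 0.60 in the 3 pairs; RXRG differed by 2.02 in the first repeat and 4.46 in the later ones, and SOX2 by -4.07 and -1.83. In the test between array versions, 10 of its members were higher and 1 lower in the later repeats (camera adjusted p = 3.9e-09; adjusted p = 0.55 with an estimated correlation). Of 11 MHC class II genes, HLA-DQA1 (-2.92, SE 0.79) and the invariant chain CD74 (from 9.46 in WM115 to 7.46 in WM266-4, SE 0.53) fell, and 0 passed adjusted over the list alone; the list's median was -2.58 in the first pair and -0.34 and -0.01 in the later pairs. The first pair gave -5.71 for HLA-DQA1 and -3.80 for CD74, and without WM115 replicate 1 or WM266-4 replicate 1 their differences were -1.52 and -1.09. Camera adjusted p values were 0.80, 0.40, 0.86, 0.11, 0.28 and 0.090. The calls of DSP (adjusted p up to 0.12), CD68 (0.094), CD74 (0.091) and HLA-DQA1 (0.088) were lost without WM115 replicate 2 or 3 or WM266-4 replicate 2 or 3. With a robust prior those of DSP (0.0513), CD74 (0.066) and HLA-DQA1 (0.071) were lost, and that of HLA-DQA1 also without the filter on dim genes (0.0502) and with the mean of a gene's rows (0.14).

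Both array versions gave an estimate of the same difference. Of 3913 genes called in the 2.1 arrays alone, among the genes that passed the filter over all 6 arrays, 86.8% had the same sign in the first-repeat pair on the 1.0 arrays, against 70.8% of all 12427 tested genes. Across genes, which are not independent replicates, the differences correlated with Pearson's r = 0.66 and a Spearman coefficient of 0.61. TYR differed by 7.28, 6.89 and 6.56 in the 3 pairs and IL1B by -5.83, -7.24 and -6.52. The first repeat held 1 array per line, so a test between versions takes its error from repeats 2 and 3 alone. Within a line, replicates 2 and 3 differed from each other with an SD of 0.22 or 0.26 log2. From replicate 1 they differed with an SD of 0.31 to 0.34. An array-version effect had been removed gene by gene, so these last SDs do not measure how far replicate 1 lay from the others. The spread of first-repeat arrays is thus not measured. In a limma test of the difference between versions, added after the data were examined, 681 genes passed an adjusted p of 0.05. Among them were 29 of the 105 genes named by rule; COL1A2 differed by 1.85 in the first repeat and 5.79 in the later ones, and PMEL by 7.42 and 4.29. Of the 28 lists, 7 passed this test by camera and 0 with an estimated correlation. Besides the pigmentation and neural crest lists, these were MHC class II (adjusted p = 4.9e-09), collagens and matrix proteins (0.012), matrix proteases and inhibitors (0.025), MAPK output (0.025) and leukocyte markers (0.048), each at an adjusted p of 0.61 with an estimated correlation.

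**Figure D3:**
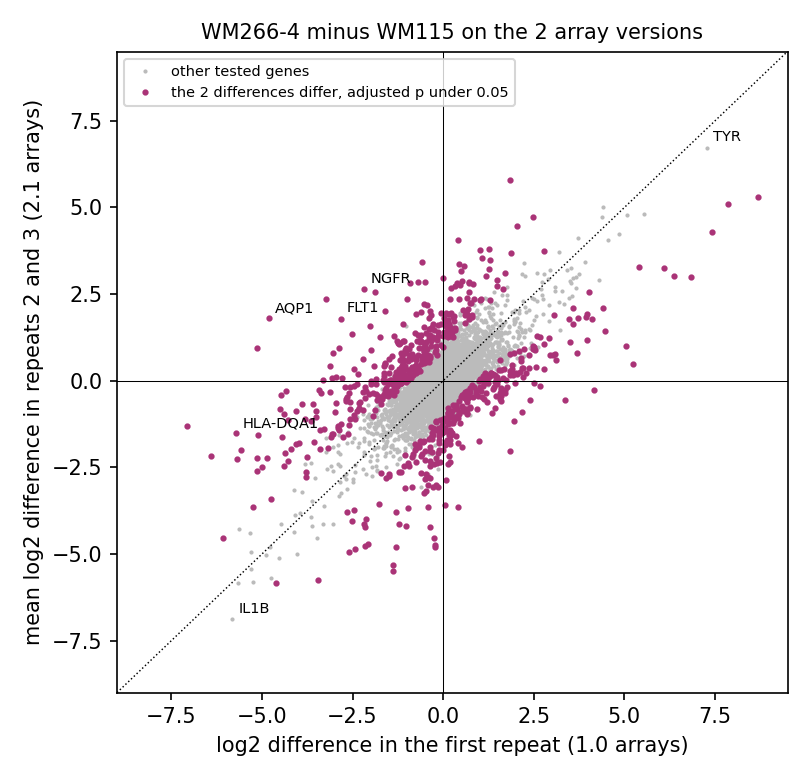
Log2 difference between WM266-4 and WM115 in the first repeat (1.0 arrays) against its mean in repeats 2 and 3 (2.1 arrays), one point per tested gene, with the 681 genes whose differences differed between versions in purple and a dotted line of equal values. TYR and IL1B lay near that line, and AQP1, NGFR and FLT1, labelled after their values were seen, had opposite signs on the array versions.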

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

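The fit without an array-version term and the synonym rule for lists were chosen after the data were examined; the other alternatives were planned. The count of 3341 genes became 972 with a difference of at least 1 log2 and 1275 at an adjusted p under 0.01, both from the stricter threshold, and it ran from 1381 to 3924 on leaving out each array. Of the genes called without WM266-4 replicate 2, 1363 were among the 3341. It was 3915 on the 2.1 arrays alone, with the filter taken over those arrays, 4126 of 37532 unnamed probe sets in the 2.1 value table, and 4709 without the array-version term. SNX18 kept its direction throughout. It missed the threshold at -0.58 without a filter (more genes tested), at -0.57 after quantile normalization and at -0.58 with the replicate block (adjusted p = 0.075), and ran from -0.78 to -0.43 on leaving out each array, with adjusted p from 0.0047 to 0.154. CDC42 turned to -0.034 on the 2.1 arrays alone, and ran from -0.034 to 0.13 on leaving out each array. The number of gene lists called rose from 5 to 11 without the filter on dim genes and was 0 with an estimated correlation. Where no cause is given, the cause was not tested. The replicate number as a block lowered the count to 2394; the numbers were treated as shared numbers only. The deposited centring forces the correlation of same-numbered deviations in the first repeat (-0.998) and enters those of repeats 2 and 3 (-0.26 and -0.40); no array correlated best with its own number, and in the uncentred 2.1 value table repeats 2 and 3 gave 0.163, so pairing was neither shown nor excluded. RHOA and the 5 lists kept their direction under the alternatives run, and the share of genes with one sign on both array versions was 86.7% without the filter and 87.1% at the 50th percentile. Of 102 other genes named by rule, 75 were called under every alternative fit of the gene-named table in which they were tested and none reversed. The stricter thresholds were not applied to them. These genes had been chosen by their calls in the main fit, which favoured both results in advance. Signal over background was not assessed, so the dim-gene filter stands in for it.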

Other observations

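Every explanatory test in this part was chosen after the results were seen, on the data that had shown the pattern, including the window size, the thresholds and the test between array versions. The reading of the MHC class II test was changed after its result was known, because the first rule would have counted any mixed outcome in favour of wrongly joined rows. The test on SNX18 was added after its neighbours had been seen and replaced a test on MHC class I genes among the patterns weighed; that result is given below as a value.

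Gene families formed by the start of the symbol gave further groups. Of 210 families with at least 8 tested members, 4 passed an adjusted p of 0.05 by camera with the preset correlation, and none of the 4 passed with an estimated one (adjusted p = 0.998 each). Ribosomal protein genes had a median of 0.25 for RPL genes (11 of 44 rose, 1 fell) and 0.29 for RPS genes (12 of 40 rose, 1 fell). Of 10 MCM genes, which encode DNA replication factors, 6 rose, with a median of 0.54. Zinc finger genes with ZNF symbols had a median of -0.14, and 59 of 368 fell while 21 rose. Medians kept their sign after quantile normalization and median centring.

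MHC class I genes inside the MHC region had a lower median difference than the genes between them, which were themselves shifted down. In the gene order of GRCh38.p14, 11 members had a median of -0.70 and 93 other genes between them, with MHC class II genes left out, had a median of -0.16, with 25 fallen and 0 risen (difference of medians -0.54, permutation p = 0.0015, two-sided, 1e+05 resamples). The permutation takes genes as independent, which HLA genes with similar probes may not be. Of all 20 members, 6 lay in runs of at least 2 windows of neighbouring genes (as below, here with a median of -0.3 or lower), and these held 4 of the 9 that fell. The 9 members elsewhere in the genome had a median of -0.18.

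The count of called genes was set against other splits of the 6 arrays into groups of 3. The real split called 3341 genes and the highest of the other splits 0. Only 1 of the 10 splits, the real one, called as many, and 10 splits are too few for a share under 0.05. Every other split put both lines in each group, so the line difference entered the error and made calls unlikely. The contrast of 3341 with 0 therefore does not decide about chance.

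The difference between the lines itself differed between the first repeat and repeats 2 and 3 for 681 genes, 305 of them with opposite signs. The nerve growth factor receptor NGFR was lower in WM266-4 by -2.17 in the first repeat and higher by 2.64 in the later ones, the water channel AQP1 went from -4.81 to 1.80, and 9 of 11 MHC class II genes had a higher value later; an exchange of the first-repeat arrays would have turned most signs, yet 90.0% of genes called with at least 1 log2 in the 2.1 arrays had the same sign in the first pair, and weaker probes on one version cannot give the 20 genes with opposite signs and at least 1 log2 in both. Weaker probes stay open for the 376 genes with the same sign. The HLA class II genes, CD74 and CIITA all had a higher value later, from 1.52 log2 for CIITA to 4.19 for HLA-DQA1. CTSS and IFI30 passed the test in the opposite direction, by -2.54 and -1.57. The other 9 were set apart after their direction was seen, so their shared direction does not decide about wrongly joined rows. Wrongly joined rows stay open for all 11 genes. A different state of the cultures may account for the 681 genes, but array version, RNA kit and culture changed together and cannot be told apart, and whether the deposited values were rescaled within a version was not tested.

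Runs of neighbouring genes shifted together: in the gene order of GRCh38.p14, 22 of 299 windows of 40 genes had an absolute median of at least 0.4, against at most 0 in 1000 shuffled orders; the genes from TUBA3C to LAMP1 had a median of 0.63 (121 of 200 rose, 5 fell) and those from IQSEC3 to SCAF11 one of -0.43 (80 of 160 fell, 14 rose). The first of these runs had 0.40 in the first repeat and 0.73 in repeats 2 and 3, and the second -0.32 and -0.47. Of 8 runs of at least 2 windows, AGAP6 to ADK was also larger later (0.40 and 0.50). IFIT2 to GPR123 (0.41 and 0.36), SHB to PAPPA (-0.40 and -0.39) and DUSP22 to HIST1H1A (-0.60 and -0.49) were smaller later. So were ZMYND11 to WAC (0.51 and 0.44) and NOTCH4 to NFYA (-0.42 and -0.34). A fixed copy number alone predicts no change in size. Since array version and repeat changed together, the sizes do not decide whether copy number differed. Window medians of the first repeat and of repeats 2 and 3 correlated at 0.865 across windows, which argues against an artefact of one array version, and all 22 windows stayed at 0.3 or more after the trend with signal level was removed. A candidate explanation is a different DNA copy number of these runs in the 2 lines: the 15 windows chosen in the first repeat alone kept their sign in the later repeats, with a median shift of 0.49 in that direction. No DNA was measured, and another shared regulation of these regions would give the same values.

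SNX18 lies in the window from GHR to IPO11, whose median of -0.33 was short of the 0.4 used above. Its 39 neighbours had a median of -0.31, 31 of them were lower in WM266-4, 16 fell and 2 rose, and 13 had a lower value than SNX18. Over all arrays SNX18 differed from the median of the others by -0.27, with an interval from -0.66 to 0.12 that leaves out the spread of the neighbours. The gap was 0.12 in the first repeat and -0.54 (interval -0.87 to -0.21) in repeats 2 and 3, while the SNX18 difference itself was not called different between the array versions (adjusted p = 0.26). A shift shared with its neighbours may be part of the SNX18 difference; whether it is the whole stays open, since the gap changed sign between repeats.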
